A study of Bradyrhizobium diazoefficiens USDA 110 with 6 samples.

How the data were processed

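The samples are 6 arrays with 2 colours each, of Bradyrhizobium diazoefficiens grown with 0.1 mM paraquat or without. They form 3 biological replicates, each hybridised as a pair of arrays in which the dyes of treated and untreated cDNA were swapped. Per the labels' protocols, RNA was extracted with hot phenol, copied into cDNA with random hexamers and labelled with Cy3 or Cy5.

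The deposited values are log ratios, taken here as log2, one per feature and array. The labels name no scanner, background correction, normalization, spot filter or log base, and these are not given in the sources used here. The largest size of a value in the deposited table, 7.81, would exceed the range of a 16-bit scanner (4.82 on a log10 scale) if the base were 10. Base 2 is assumed, and a natural logarithm is not excluded. All arrays have means near 0, so each was centred before deposit. The pairs of swapped arrays correlate positively, so the ratios of the swapped arrays were taken as already turned by the authors. The rule for this was a correlation above 0.3. Replicate 3 met it only just, with a Pearson correlation of 0.3005 and a Spearman correlation of 0.28, so its direction is less certain. The removal of a dye effect, described below, takes away part of the difference within pairs and so can raise these correlations. The low value of replicate 3 therefore gives no support for its direction or for agreement of its arrays. The titles put paraquat first, and so the ratio is taken as paraquat over untreated, as likely but not certain. In 3765 of 3765 features with values on all 6 arrays the mean of the arrays with paraquat in Cy5 equals that of the arrays with paraquat in Cy3 within 2e-05, so a dye effect per feature had been removed before deposit. This step is seen in the values and no label states it. Arrays of one dye orientation are therefore not independent checks of the others. Channel intensities were not used here, so the signal over background of a gene is not known, and why some values are empty is not given in the sources used here.

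Features were named through the platform's annotation of the probes. Of 8480 features 8462 had 1 gene, 0 had several and 18 had none, and 1469 belonged to a gene with a symbol other than its locus tag. Features of one gene were averaged on each array, which gave 8269 genes. Of 191 genes with more than 1 feature, 90 had features whose means differ in sign. The RefSeq gene table at hand is of another assembly and shares 0 locus tags and 0 Entrez identifiers with these features, so symbols could not be updated and no coordinates are given. Locus tag numbers give the gene order.

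The arrays of a pair were averaged, and limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings) tested the mean of the 3 replicates against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 7486 genes with a value in all 3 replicates were tested and 783 were left out. Of the tested genes 3740 had values on all 6 arrays. For the rest, at least 1 replicate value came from a single array, where the dyes do not cancel. With 3 replicates the spread between cultures is estimated from few values, and the limma adjusted p pools information over genes. The median SD of a gene between replicates was 0.32.

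Before the data were examined, 29 gene lists were fixed as patterns of gene symbols and product names. No product names were used here, so the lists were filled by symbol alone, and 25 had the minimum of 3 measured members. Camera tested them with its preset correlation of 0.01, then with an estimated correlation, and fry was run beside it. With an estimated correlation camera also takes its p from the few degrees of freedom that 3 replicates leave. A call after adjustment was then hard to reach, whatever the correlation between genes. Counts of members called are given over all genes, where they are 0 for every list, and adjusted over the list alone. The estimated correlations of the tested lists ranged from -0.153 to 0.914.

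The rule for named genes was also fixed before the data were examined. It took the 10 largest increases and 10 largest decreases with a symbol and the same sign on all 6 arrays, described as not past the test since no gene passed, the member of each list with the lowest p, and every measured superoxide dismutase, catalase, alkyl hydroperoxide reductase and regulator of the SoxR, OxyR or Fur kind. Other genes named here were chosen after their values were seen.

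Alternatives fixed before the data were examined were a fit of all 6 arrays with a dye term and the replicate as a block (correlation within replicates 0.612), arrays of one dye orientation alone, centring, scaling and quantile normalization of the arrays, other filters on missing values, robust moderation, an unmoderated statistic, an unadjusted threshold, features in place of genes, and leaving out each replicate. Scaling used the median absolute log ratio, which is what limma applies to ratios. Treating the 6 arrays as independent, and removing 3 genes that lists took in by spelling, were added after the data were seen. Correlation between neighbouring genes was tested against 10000 random orders.

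The limma test was tested on simulated data for this comparison, with 7486 genes, 3 replicates and 200 genes changed, 50 of each size. With gene variances drawn from the prior that limma fitted, it recovered 4% of changes of log2 size 1, 80% of size 2, 92% of size 3 and 96% of size 4, with 1 false call among 137. The simulation run first used the moderated variance of each gene. It recovered 38%, 98%, 96% and 98% and made 19 false calls among 184, or 10.3%, above the rate aimed at, and the draw from the prior was added after this was seen. In simulated data with no effect camera called 0 of 25 lists. These simulated genes were independent of each other, unlike the genes measured. The prior SD was 0.328. Some genes with large ratios in the data had far larger SDs, such as 2.04 for fla (bll6865) and 1.46 for groEL (blr5626). Others had smaller ones, such as 0.15 for bkdA1 (blr6331). The recovery rates therefore need not hold for genes that vary strongly between replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

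The median log2 ratio per array was -0.07 and -0.02 in replicate 1, 0.06 and 0.05 in replicate 2, and 0.01 and 0.00 in replicate 3, with paraquat in Cy5 first. The log base (scale) and the direction of the ratio stay unknown in the sense given above, and the method of centring is not given in the sources used here.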

Results

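Transcript levels were compared between cells of Bradyrhizobium diazoefficiens grown with paraquat and untreated cells. This soil bacterium fixes nitrogen in the root nodules of soybean, and paraquat is a herbicide that passes electrons to oxygen and so forms superoxide inside cells. The treated cultures grew in arabinose-gluconate medium with 0.1 mM paraquat during all of their growth, so the comparison asks how transcript levels differed after long exposure. RNA of 3 independent biological replicates was hybridised on 6 arrays with 2 dyes each, as a pair with swapped dyes per replicate. The number of replicates limits the precision of every value (n = 3).

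The values are log ratios of 8480 features per array, named by 8269 genes. The log base is not given in the sources used here and base 2 is assumed, so every fold rests on that assumption. The direction is taken as paraquat over untreated, which is likely because the sample titles put paraquat first, but it is not certain. The median log2 ratio of an array was -0.07 and -0.02 in replicate 1, 0.06 and 0.05 in replicate 2, and 0.01 and 0.00 in replicate 3, with the array of Cy5-labelled paraquat cDNA given first. In the same order, 11 and 25 features had no value in replicate 1, 687 and 766 in replicate 2, and 3023 and 2271 in replicate 3. Across features, the arrays of a pair correlated with r = 0.82 in replicate 1, 0.91 in replicate 2 and 0.30 in replicate 3. A dye effect removed before deposit can raise these values, so the low one of replicate 3 does not show that its arrays agree. Across the 7486 genes tested, the mean ratios correlated with r = 0.48 between replicates 1 and 2, 0.03 between 1 and 3, and 0.23 between 2 and 3. Genes are not independent replicates, so these correlations describe the arrays.

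Among genes with a symbol and 1 sign on all 6 arrays, the highest ratios belonged to flagellar genes, chaperonin genes and a gene of branched-chain amino acid breakdown. The flagellin gene fla (bll6865) had a mean log2 ratio of 4.24 ± 2.04 (SD, n = 3), or 18.8-fold, and was above 0 on 6 of 6 arrays. Its mean was 3.31 without replicate 2 and 5.33 without replicate 3, so the fold depends on which replicates are used. The chaperonin gene groEL (blr5626) stood at 3.06 ± 1.46, and bkdA2 (blr6332), for a subunit of branched-chain 2-oxoacid dehydrogenase, at 2.68 ± 0.74. The lowest means were those of nosZ (blr0315), for nitrous oxide reductase, at -1.69 ± 2.42, and of cycL (blr3128), named for cytochrome c maturation, at -1.19 ± 1.11. None of these differences passed the test: limma called 0 of 7486 genes at an adjusted p below 0.05, the lowest adjusted p being 0.0859.

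At an unadjusted p below 0.05, limma gave 880 genes, 558 above 0 and 322 below 0, where chance alone would give 374.3. This count was 469 without replicate 1, 307 without replicate 2, which is below the 375 of chance there, and 1527 without replicate 3, so its excess over chance depends on the replicates used. Of the 880 genes, 240 differed at least 2-fold, 171 above 0 and 69 below. That number was 239 without replicate 1, 121 without replicate 2, 659 without replicate 3 and 73 with the unmoderated statistic. The gene with the lowest p was bkdA1 (blr6331), which lies next to bkdA2, with a mean log2 ratio of 3.28 ± 0.15 (SD, n = 3), or 9.69-fold, above 0 on all 5 arrays that measured it. When limma was fitted to all 6 arrays with a dye term and the replicate as a block, 3 genes rose and 0 fell: bkdA1 with an adjusted p of 0.00812, and blr1602 and blr6846, which carry no symbol, with 0.0164 each. Their mean log2 ratios were 2.52 ± 0.30 for blr1602 and 3.01 ± 0.78 for blr6846, each with values on 5 arrays. These 3 genes lie outside the rule for named genes and were chosen after their values were seen.

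The rest of the 10 highest means of genes with a symbol and 1 sign on all 6 arrays belonged to 6 flagellar genes and a second groEL. The hook protein gene flgE (bll6858) stood at 2.96 ± 1.14, flgD (bll6853), for hook assembly, at 2.88 ± 1.49, and the rod gene flgC (bll6875) at 2.20 ± 1.24. The P-ring gene flgI (bll6871) had 2.02 ± 0.76, groEL (blr7533) 1.95 ± 1.13, fliE (bll6874) 1.91 ± 0.52 and the export gene flhB (bll6877) 1.56 ± 0.78. Among the decreases, the mean was -1.02 ± 0.77 for mvrA (blr3831), a symbol that stands for methyl viologen resistance, methyl viologen being paraquat. It was -0.92 ± 0.48 for msrA (blr7043), for methionine sulfoxide reductase, and -0.91 ± 0.46 for hyfF (blr6342). Values between -0.79 and -0.61 were measured for betB (blr3776), acd (blr1158), panC (blr5162), the protease gene lon (bll4942) and hisC (blr6225). For nosZ the mean rests on replicate 2, where it stood at -4.49, against -0.25 and -0.33 in replicates 1 and 3, and without replicate 2 the mean of cycL was -0.58. The adjusted p of the 20 genes ranged from 0.362 to 0.503 in limma.

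**Figure D1:**
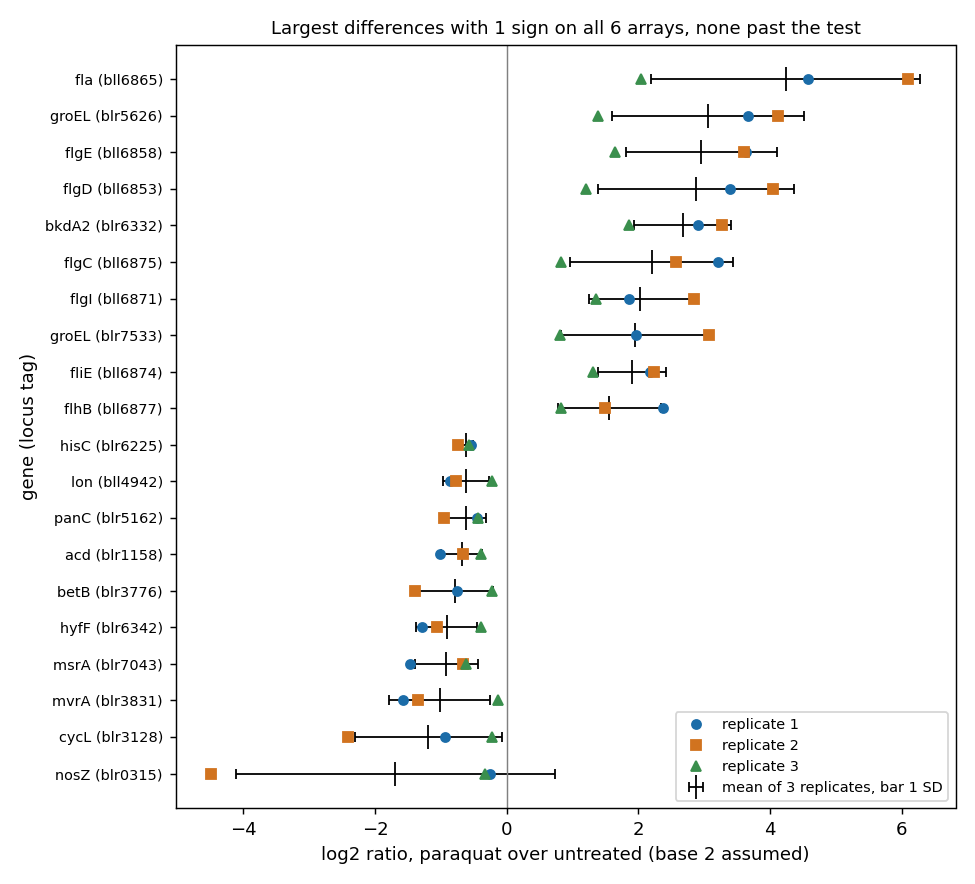
Mean log2 ratio of paraquat over untreated for the 10 highest and 10 lowest genes with a symbol and 1 sign on all 6 arrays (vertical mark, bar 1 SD), with each replicate as a point. The means run from 4.24 for fla to -1.69 for nosZ, and none passed the test.

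Most genes of the lists for ribosomal proteins, translation factors, ATP synthase and the TCA cycle had means above 0. All 52 measured genes of the ribosomal protein list had a mean above 0, 47 of them in each of the 3 replicates. The median log2 ratio of the list was 0.84, or 1.79-fold. Of 21 measured genes with symbols that begin with rps, 20 were on this list and 20 had a mean above 0. Adjusted over the list alone, 39 of the 52 rose in limma and 0 fell. The median was 0.88 in replicate 1, 0.95 in replicate 2 and 0.56 in replicate 3. The member with the lowest p was rpsQ (bsl5391) at 1.12 ± 0.09 (SD, n = 3). All 8 genes of ATP synthase, the enzyme that makes ATP from the proton gradient, were above 0 with a median of 1.13, or 2.20-fold, and 7 of them rose when adjusted over the list alone, among them atpA (bll1188) at 1.61 ± 0.48 and atpB (bll1185) at 1.99 ± 1.39. Of 7 translation factor genes 6 were above 0, with a median of 0.53, and 3 rose when adjusted over the list alone: tuf (bll5402) at 1.20 ± 0.12, fusA (bll5403) at 1.15 ± 0.41, which encode elongation factors, and the release factor gene prfA (blr0218) at 0.53 ± 0.10. The list named for tRNA synthetases as well held none of them. Of 11 TCA cycle genes 10 were above 0, with a median of 0.70 and 0 members called over the list alone, and the 4 succinate dehydrogenase genes sdhA (blr0514), sdhB (blr0515), sdhC (blr0512) and sdhD (blr0513) had means of 0.99, 1.32, 0.93 and 1.18. The TCA cycle median was 0.22, 0.99 and 0.34 in replicates 1, 2 and 3, and the median of the means was 0.28 without replicate 2, where sdhC stood at 2.26. The ATP synthase median was 1.44, 1.76 and 0.31 in the replicates.

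With its preset correlation, camera on these limma values called the ribosomal protein list (adjusted p = 3.31e-25), the ATP synthase list (adjusted p = 9.18e-06), the TCA cycle list (adjusted p = 0.000869) and the translation factor list (adjusted p = 0.0255) as higher. With an estimated correlation between genes, camera's adjusted p was 0.732 for each of these 4 lists and none was called, the unadjusted p of the ribosomal protein list being 0.0396. The estimated correlation of the translation factor list was -0.068, below the preset 0.01, yet camera's unadjusted p for it went from 0.00922 to 0.115. That setting leaves few degrees of freedom with 3 replicates. Its lost calls therefore do not show that correlation between genes explains these lists. Without replicate 1 the translation factor list had an adjusted p of 0.0973, and without replicate 3 of 0.0683. Ribosomal proteins and ATP synthase are groups that the study of these arrays is known to have discussed, so their counts and direction here are not independent evidence.

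**Figure D2:**
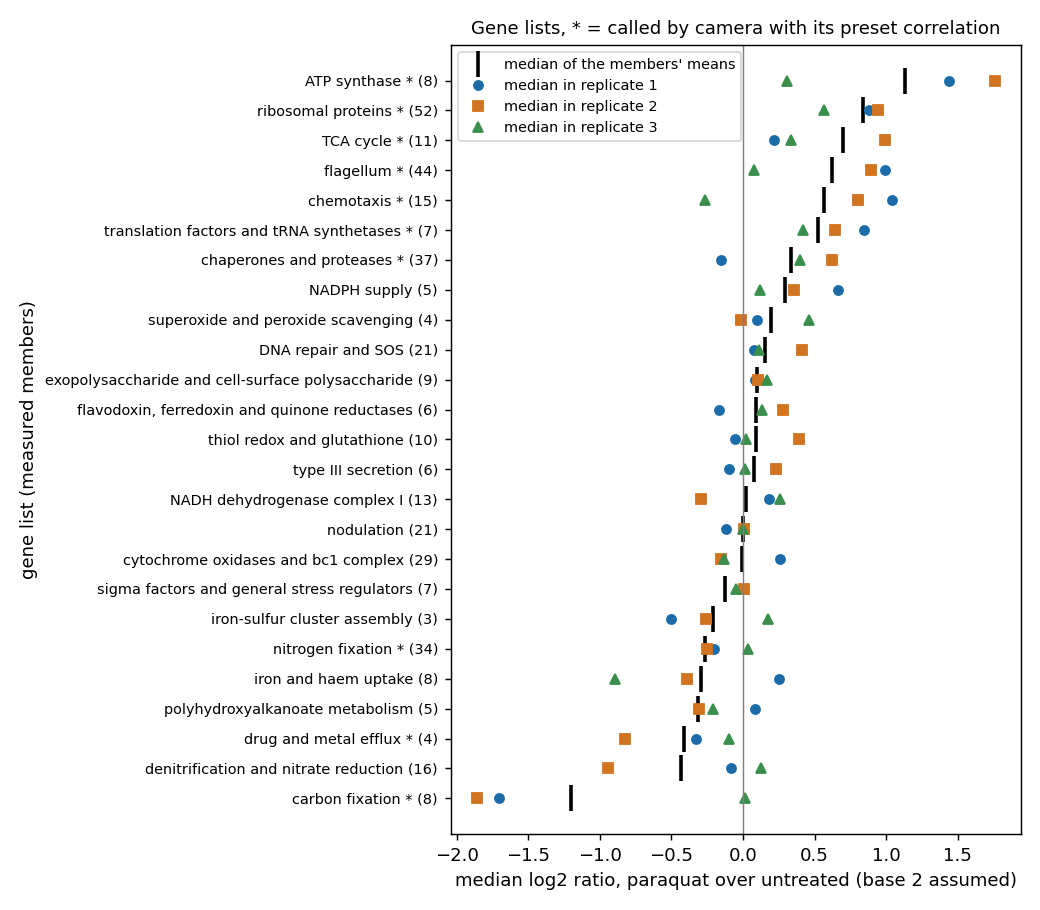
Median log2 ratio of paraquat over untreated of each tested gene list (vertical mark, median of the members' means) and its median in each replicate (points), with the number of measured members in brackets and an asterisk at lists called by camera with its preset correlation. The medians run from 1.13 for ATP synthase to -1.20 for carbon fixation, where replicate 3 stands at 0.01.

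Of 44 flagellum genes 39 had a mean above 0, with a median log2 ratio of 0.62, or 1.54-fold. Adjusted over the list alone, 10 rose and 0 fell in limma, and all 10 carry locus tags from bsl6852 to blr6884. Besides flgE, flgD, flgC, flgI, fliE and flhB these were the motor genes motC (bll6861) at 1.27 ± 0.32 (SD, n = 3), fliG (bll6878) at 1.65 ± 0.53 and fliN (bll6879) at 1.39 ± 0.62, and the L-ring gene flgH (bll6869) at 1.46 ± 0.56. The flagellin gene fla (bll6865) lies in the same stretch but its symbol falls outside the list. Its neighbour bll6866, without a symbol, stood at 4.29 ± 1.80, and no product name or sequence was used here, so signal shared between similar neighbouring genes is not excluded. The median of the flagellum list was 1.00, 0.89 and 0.08 in replicates 1, 2 and 3, and the median of the means was 0.94 without replicate 3.

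Chemotaxis genes, whose products steer the flagella, were above 0 in 14 of 15 cases, with a median of 0.57 and 0 members called over the list alone. Their median was 1.04 in replicate 1 and 0.80 in replicate 2 but -0.26 in replicate 3, and a single member was above 0 in all 3. The receptor methyltransferase gene cheR (blr2196) had the lowest p, at 0.56 ± 0.17. The list took in tlpA (bll1380) by its spelling, at -0.12 ± 0.82, and was called without it too. Camera with its preset correlation called the flagellum list (adjusted p = 1.22e-10) and the chemotaxis list (adjusted p = 0.00484) as higher. With an estimated correlation the adjusted p was 0.732 for both. Without replicate 1 the chemotaxis list had a median of 0.29 and an adjusted p of 0.127, and without replicate 3 a median of 1.01. The study is known to have discussed chemotaxis on these arrays, so its direction is not independent evidence.

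**Figure D3:**
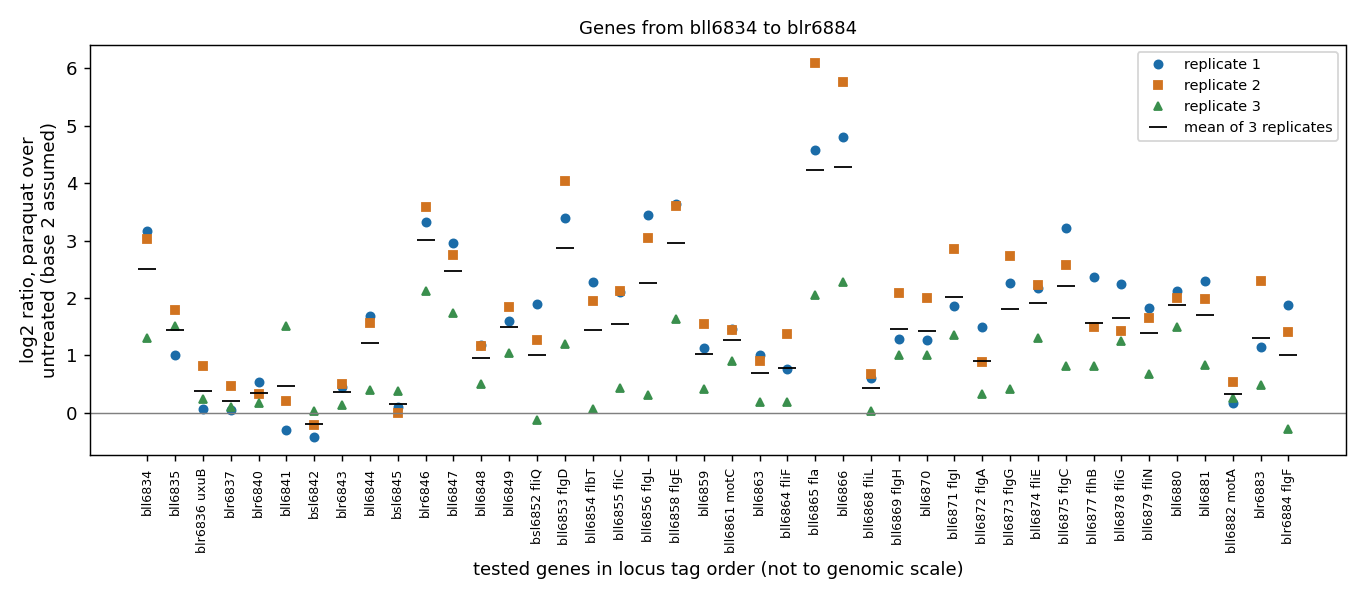
Log2 ratio of paraquat over untreated of the tested genes with locus tags from bll6834 to blr6884 in tag order, for each replicate (points) and as the mean (horizontal mark). The highest means are those of bll6866 at 4.29 and fla at 4.24, and replicate 3 reaches 2.28 and 2.05 there.

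All 4 measured groEL and 5 groES genes, which encode the chaperonin and its lid, had means above 0, and the highest besides groEL (blr5626) were groES (blr5625) at 3.08 ± 1.72 and groES (bsr7532) at 2.66 ± 1.05. Besides groEL (blr7533) at 1.95 ± 1.13, the other measured groEL copies were near 0, with 0.03 ± 0.61 for blr5227 and 0.16 ± 0.24 for blr6979. The chaperone gene dnaK (blr0678) had 0.64 ± 0.97. Genes of ATP-dependent proteases lay on both sides of 0, with lon (bll4942) at -0.61 ± 0.34 and clpX (bll4943) at -0.55 ± 0.06 but clpP (bll4944) at 0.47 ± 0.12, hslU (bll0646) at 0.49 ± 0.46 and hslV (bll0649) at 0.47 ± 0.51. Of 37 chaperone and protease genes 26 were above 0, with a median of 0.33 and 0 members called over the list alone. The median was -0.15, 0.62 and 0.40 in replicates 1, 2 and 3, and the median of the means was 0.52 without replicate 1 and 0.15 without replicate 2. Camera with its preset correlation called the list as higher (adjusted p = 0.0183), the adjusted p was 0.732 with an estimated correlation, and without replicate 3 it was 0.226. Copies of groEL are similar in sequence, so the signal of each is uncertain.

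The genes listed for removal of superoxide and peroxide, which included an iron store gene, did not move together. Of 4 measured genes, bfr (bll6680), for the iron store bacterioferritin, rose when adjusted over the list alone, with a mean log2 ratio of 0.99 ± 0.53 (SD, n = 3). The superoxide dismutase gene sodF (bll7774) fell when adjusted over the list alone, at -0.81 ± 0.40, although 4 of its 6 arrays lay below 0 and 2 above. The alkyl hydroperoxide reductase genes ahpC (bll1777) and ahpD (bll1776) stood at 0.10 ± 0.06 and 0.29 ± 0.50. In limma over all genes the adjusted p was 0.403 for bfr and sodF, 0.781 for ahpC and 0.615 for ahpD. Camera's adjusted p for the list was 0.693, and its median of 0.19 was not called. The median of the means was 0.24 without replicate 1, 0.29 without replicate 2 and 0.04 without replicate 3. Of 2 regulators of the Fur family, fur (bll0797), the ferric uptake regulator, rose when adjusted over these 2 genes alone, at 0.81 ± 0.49, and irr (bll0768), a haem-responsive iron regulator, stood at -0.23 ± 0.21. No catalase, soxR or oxyR gene was found by symbol among the features, and ohr (blr1196), for organic hydroperoxide resistance, lacked a value in at least 1 replicate, so these were not analysed here.

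Among 10 thiol redox and glutathione genes 7 were above 0, and the list's median of 0.09 was not called (camera adjusted p = 0.530). It was 0.16 without replicate 1, -0.0058 without replicate 2 and 0.16 without replicate 3. The lowest p belonged to gshB (bll0668), for glutathione synthetase, at 0.74 ± 0.31. Of the msrA genes, blr7043 stood at -0.92 and blr0834 at 0.07. Both measured genes of the list for arabinose and gluconate breakdown, kdgA (blr3923) at 1.31 ± 0.71 and kdgK (blr3922) at 0.79 ± 0.44, rose when adjusted over these 2 genes alone. The lists of regulators and of sugar breakdown had fewer than 3 measured members and were not tested as groups.

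Genes of carbon dioxide fixation were lower with paraquat in replicates 1 and 2. All 8 members of the list had a mean below 0, with a median log2 ratio of -1.20, which is 2.30-fold lower. The median was -1.70 in replicate 1, -1.86 in replicate 2 and 0.01 in replicate 3, and the median of the means was -1.81 without replicate 3. The lowest were cbbX (blr2587) at -1.99 ± 1.55 (SD, n = 3) and cbbA (blr2584) at -1.94 ± 1.77, and cbbL (blr2585) and cbbS (blr2586), for the subunits of RuBisCO, stood at -1.34 ± 1.26 and -1.21 ± 1.32. The list took in coxM (bll3785) by its spelling, at -0.03 ± 0.29. Camera with its preset correlation called the list as lower (adjusted p = 0.000848), with 0 members called over the list alone in limma. With an estimated correlation the adjusted p was 0.732.

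Of 34 nitrogen fixation genes 24 had a mean below 0, with a median of -0.26 and 0 members called over the list alone. The nitrogenase genes nifH (blr1769), nifD (blr1743) and nifK (blr1744) stood at -0.27 ± 0.42, -0.06 ± 0.59 and -0.06 ± 0.09. Far lower were genes named fix that encode the high-affinity cytochrome oxidase and its assembly, such as fixQ (bsr2765) at -2.17 ± 3.88 and fixP (blr2766) at -1.84 ± 3.59, and these means rest on replicate 2, where they had -6.66 and -5.99. In replicate 2 the median over 11 genes, fix genes of this kind together with nap genes for periplasmic nitrate reductase, was -4.40, against -0.49 in replicate 1 and 0.09 in replicate 3. These 11 genes were chosen after their values were seen. The ferredoxin-like gene frxA (bsr1760) had the lowest p, at -0.62 ± 0.31. Camera with its preset correlation called the list as lower (adjusted p = 0.0108), and with an estimated correlation the adjusted p was 0.732. Without replicate 2 it was 0.575 with a median of -0.02, and the median was -0.09 without replicate 1 and -0.43 without replicate 3.

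**Figure D4:**
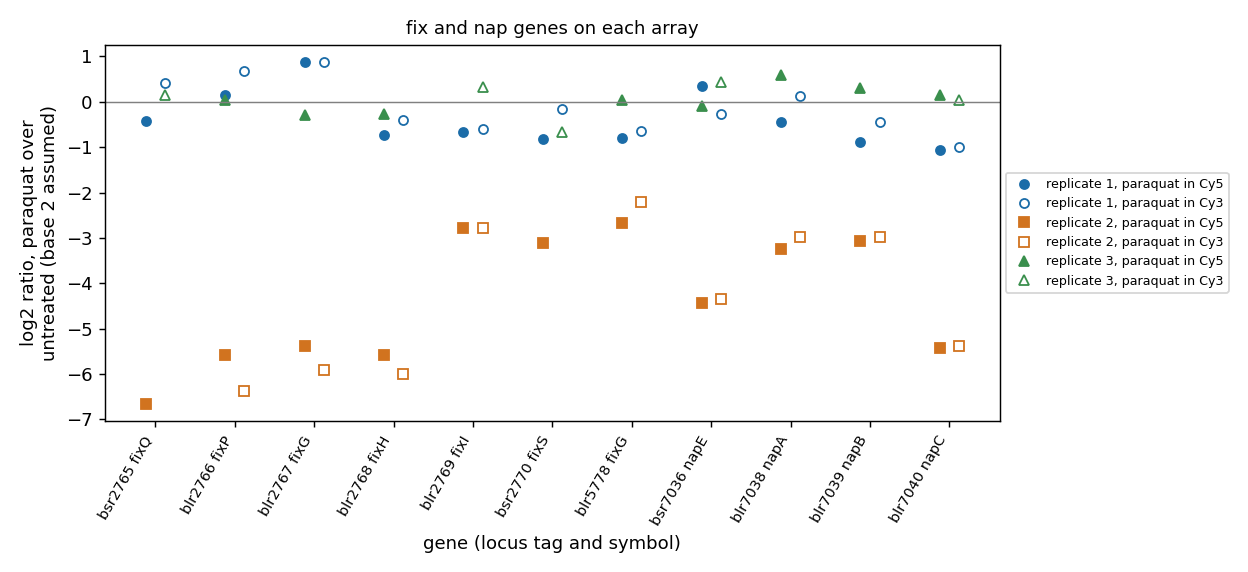
Log2 ratio of paraquat over untreated of 11 fix and nap genes on each array, with filled points for arrays with paraquat in Cy5 and open points for Cy3. The medians of the arrays of replicate 2 are -4.44 and -4.35, and those of the other arrays lie between -0.66 and 0.14.

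Denitrification and nitrate reduction genes had a median of -0.43 over 16 members, 12 of them below 0, and were not called (camera adjusted p = 0.0522). Their medians were -0.09, -0.94 and 0.12 in replicates 1, 2 and 3, and without replicate 2 the median of the means was 0.04. Without replicate 1 the adjusted p was 0.00243 and without replicate 3 it was 0.0355. The lowest p in the list was that of nosL (blr0319), at -0.41 ± 0.22. All 4 efflux genes, which export drugs, were below 0, with a median of -0.41 and 0 members called over the list alone, and emrA (bll6622) stood at -0.72 ± 0.54. Camera with its preset correlation called this list as lower (adjusted p = 0.0255), with an adjusted p of 0.732 with an estimated correlation and of 0.155 without replicate 2, where the median was -0.26.

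The remaining lists were not called by camera. All 8 iron and haem uptake genes had means below 0, with a median of -0.30 and an adjusted p of 0.0769. But the medians were 0.25, -0.39 and -0.89 in replicates 1, 2 and 3, and without replicate 1 camera's adjusted p was 7.22e-05. The median of the means was -0.65 without replicate 1, -0.29 without replicate 2 and -0.10 without replicate 3. The median was 0.30 for 5 NADPH supply genes (0.14 without replicate 1 and 0.57 without replicate 3), where dme (blr4145), for malic enzyme, stood at 0.61 ± 0.50 and pntB (bll7124), for transhydrogenase, at 0.55 ± 0.38. It was 0.15 for 21 DNA repair genes, 0.10 for 9 genes of surface polysaccharides, 0.09 for 6 ferredoxin and quinone reductase genes and 0.08 for 6 type III secretion genes. Without replicate 2 these medians were 0.03, -0.0053, 0.04 and 0.0093, and that of the ferredoxin list was 0.22 without replicate 1 and 0.02 without replicate 3. All 3 genes of the iron-sulfur cluster assembly list were named nifS and are on the nitrogen fixation list too, so the 2 lists are not separate results. The median was -0.12 for 7 sigma factor genes, -0.21 for 3 genes of iron-sulfur cluster assembly and -0.31 for 5 genes of polyhydroxyalkanoate storage. Without replicate 1 these were -0.06, -0.06 and -0.39, without replicate 2 they were 0.01, -0.16 and -0.06, and without replicate 3 they were -0.09, -0.40 and -0.23. Single members with the lowest p of their lists were exoU (blr7573), of polysaccharide synthesis, at 1.21 ± 0.53, fdx (bll5885), a ferredoxin gene, at 0.94 ± 0.90, phbA (blr3724) at -0.31 ± 0.16, nifS (blr1756) at -0.26 ± 0.36, rhcC1 (bll1811) at -0.59 ± 0.41, the heat-shock sigma factor gene rpoH1 (blr5231) at 0.29 ± 0.20, exbD (bll7072) at -0.69 ± 1.02 and mutA (bll3056), which the repair list took in by its spelling, at 0.41 ± 0.09.

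Respiratory chain and nodulation lists had medians near 0, and no direction is given for them. The median of 13 genes of NADH dehydrogenase was 0.02 and turned negative when the arrays were scaled to one median absolute log ratio. That of the 29 genes listed for cytochrome oxidases and bc1 was -0.01 and turned positive with that scaling and with quantile normalization, and camera gave this list the opposite sign to its median. The list held only cox, cyc, cyo and fix symbols, among them cycL, named for cytochrome c maturation. Its near-0 median mixed 14 members above 0 and 15 below, from coxA (blr1171) at 1.48 ± 1.30 to fixQ (bsr2765) at -2.17 ± 3.88. Both fixQ and fixP are on the nitrogen fixation list too. The median of 21 nodulation genes was 0.00, their mean was 0.06 and camera's sign was negative. Within these lists nuoF (bll4912) stood at 0.51 ± 0.17, cyoB (blr0150), of the quinol oxidase, at 0.76 ± 0.34 and nodN (blr3959) at 1.18 ± 1.21. The lists for ABC transporters and for transposases had 0 members by symbol, so transport, which the study is known to have discussed, was not analysed here as a group.

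Over all 25 lists tested, camera with its preset correlation called 7 as higher and 3 as lower. Camera with an estimated correlation and the rotation test fry each called 0, where 1 list and 3 lists had an unadjusted p below 0.05. Few degrees of freedom remain for camera with an estimated correlation, so its 0 does not show that correlation between genes explains the calls.

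Genes next to each other had similar ratios. Across 4576 pairs of genes with consecutive locus tags on the same strand, as in operons, the mean log2 ratios correlated with r = 0.54, against at most 0.06 in 10000 random orders of the genes (one-sided permutation p = 1e-04, the smallest they can give). For 2246 consecutive pairs on opposite strands r was 0.21. These correlations are across genes, which are not independent replicates.

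In limma 0 of 3740 genes measured on all 6 arrays had a dye effect at an adjusted p below 0.05, and 0 at an unadjusted p below 0.05. This count is 0 by construction, because the mean of the Cy5 arrays equalled that of the Cy3 arrays within 2e-05 in 3765 of 3765 features with values on all arrays. Of 4712 features with values on only some arrays, 0 had equal means within that tolerance, and the median difference was 0.12. With 1 replicate left out the equality no longer holds. The limma test then gave an adjusted p below 0.05 for 0 of 3743 genes without replicate 1, 0 of 3956 without replicate 2 and 35 of 6924 without replicate 3. Where all arrays have values, the dye differences of the 3 replicates sum to 0. Those of replicates 1 and 2 then mirror replicate 3, with correlations across genes of -0.78 and -0.78. A dye effect in the 35 genes cannot be told apart from a trace of this step.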

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

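The treatment of the 6 arrays as independent samples, and lists without coxM, tlpA and mutA, were chosen after the data were seen. The count of genes changed by paraquat was 0 in limma and was 0 under the alternatives not named next, each leave-one-out fit included. It became 3 with a dye term and the replicate block, 397 with the 6 arrays as independent samples, which counts each RNA as 2 replicates, and 240 at an unadjusted p below 0.05 with at least 2-fold change. Of genes changed at least 2-fold, these settings gave 3, 141 and 240. Each leave-one-out fit rests on 2 replicates and has little power, so its count of 0 genes does not show that the result is stable. The gene lists called numbered 10, and 8 to 10 with 1 replicate left out. They numbered 0 with an estimated correlation and 0 with fry. Camera with an estimated correlation has few degrees of freedom here, so its 0 decides nothing about correlation between genes. With an estimated correlation the adjusted p was 0.732 for each of the 10. With fry it was 0.184 for ribosomal proteins and translation factors, 0.412 for ATP synthase and drug efflux, 0.453 for flagellum, 0.460 for the TCA cycle and carbon fixation, 0.631 for chaperones and chemotaxis and 0.648 for nitrogen fixation. With 1 replicate left out, the adjusted p ranged from 1.28e-27 to 2.70e-18 for ribosomal proteins, 5.38e-07 to 0.000205 for ATP synthase, 0.000205 to 0.00632 for the TCA cycle, 5.48e-16 to 6.37e-06 for flagellum and 5.38e-07 to 0.00738 for carbon fixation. It passed the threshold in some of these fits only, from 6.90e-05 to 0.226 (without replicate 3) for chaperones, 0.0222 to 0.0973 (without replicate 1) for translation factors, 9.86e-07 to 0.127 (without replicate 1) for chemotaxis, 0.00153 to 0.575 (without replicate 2) for nitrogen fixation and 0.0355 to 0.155 (without replicate 2) for efflux; translation factors had 0.0683 without replicate 3. Iron and haem uptake passed without replicate 1 (7.22e-05), and denitrification without replicate 1 (0.00243) or 3 (0.0355). The count of the dye test went from 0 to 35 genes without replicate 3 and was 0 without replicate 1 or 2 (range 0 to 35). A trace of the removal before deposit cannot be told apart from a dye effect there. The direction of some uncalled lists reversed when 1 replicate was left out. Each is given with its adjusted p there and the range over the leave-one-out fits. Without replicate 1 these were NADH dehydrogenase (0.914; 0.119 to 0.963) and cytochrome oxidases (0.316; 0.206 to 0.424). Without replicate 2 they were thiol redox (0.995; 0.200 to 0.995), sigma factors (0.995; 0.507 to 0.995), denitrification (0.940; 0.00243 to 0.940) and type III secretion (0.940; 0.688 to 0.963). Without replicate 3 they were superoxide scavenging (0.963; 0.527 to 0.963), type III secretion (0.963) and nodulation (0.976; 0.934 to 0.995), and nodulation reversed with fry too (0.978). The log2 ratio of ahpD (bll1776) ranged from -0.0022 without replicate 3 to 0.46 without replicate 2. Named genes gave 28 further calls in the same direction, all with the arrays as independent samples, and the neighbour correlation lay between 0.465 and 0.582 in the alternatives run. For these changes of counts, calls and direction the cause was not tested. Signal over background is not known, and empty values, most frequent in replicate 3, limit the genes that can be tested.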

Other observations

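The comparison of the 2 flagellum clusters, the grouping of genes by symbol, both tests on replicate 3 and both tests on the fix and nap genes were chosen only after the result was seen. Most flagellum genes lay in 2 clusters. The 20 genes from bsl6852 to blr6884 had a median log2 ratio of 1.50, with 2.00, 1.81 and 0.56 in replicates 1, 2 and 3, and all 20 were above 0. The 14 genes from bll5809 to blr5838 had a median of 0.49, with 0.88, 0.77 and -0.09. The difference between the clusters was not tested on independent data.

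When genes were grouped by the first letters of their symbols, camera with its preset correlation called 26 of 101 groups, and 0 with an estimated correlation, where the lowest adjusted p was 0.863. The latter setting has few degrees of freedom, so its 0 decides little. All 5 thi genes, for thiamine synthesis, were above 0 in each replicate, with a median of 1.04. The median was 0.87 for 4 ser genes, 0.62 for 7 pyr genes, 0.50 for 13 his genes, 0.46 for 9 met genes, 0.42 for 16 fab genes and 0.34 for 12 pur genes, named for synthesis of serine, pyrimidines, histidine, methionine, fatty acids and purines. Among the further groups called were 8 trp genes with a median of 0.43 and 4 acc genes with 0.77. Some groups named for biosynthesis were not called. They included 9 ilv genes with a median of -0.04, 9 leu genes with 0.33, 7 arg genes with 0.18, 10 aro genes with 0.22 and 12 cys genes with 0.17. No common direction of biosynthesis genes was tested. All 5 rag genes were below 0 in each replicate, with a median of -0.50. A run of neighbouring genes was high too: bll5274 at 1.83, bll5275 at 2.33, blr5276 at 2.91, blr5277 at 2.46 and idnD (blr5278) at 1.48.

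The real signs of the replicates gave 880 genes at an unadjusted p below 0.05 and the highest of the other sign patterns 505, so 1 of 4 patterns gave as many. For gene lists called by camera the real signs gave 10 and the highest other 8, again 1 of 4. With 4 patterns a share under 0.05 cannot be reached.

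Replicate 3 correlated with replicate 1 at r = 0.03 across genes. Its ribosomal protein median was 0.56 (95% bootstrap interval over genes 0.50 to 0.71), of the same sign as in the other replicates. For these genes this argues against wrongly turned ratios. Genes of a list are not independent, so the interval does not measure the spread between cultures. Other called lists were mixed in replicate 3. ATP synthase (0.31), translation factors (0.42), the TCA cycle (0.34), flagellum (0.08) and efflux (-0.09) kept the sign of replicates 1 and 2. Chemotaxis (-0.26), carbon fixation (0.01) and nitrogen fixation (0.04) had the opposite sign. For chaperones and proteases replicate 3 (0.40) had the sign of replicate 2 (0.62), and replicate 1 (-0.15) had the opposite one. The arrays of replicate 3 differed more within their pair, with an SD of the dye difference of 0.68 against 0.43 and 0.44 in replicates 1 and 2. Whether larger noise explains the low correlation with the other replicates stays open, and it could be a cause. The noise variance that the differences within pairs required was 0.0352 of an observed variance of the mean of 0.492 in replicate 1. For replicate 2 it was 0.0391 of 0.832, and for replicate 3 it was 0.242 against 0.214. The required value exceeded the observed one by 0.0278 (0.00866 to 0.0479), so the assumption of independent array errors did not hold. A difference between the cultures stays open and was not tested.

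A set of 11 fix and nap genes had a median of -4.40 in replicate 2, against -0.49 in replicate 1 and 0.09 in replicate 3. Of the fix genes outside the set, 4 fixK genes were low there too, with -3.90 for bll2109, -3.97 for bll2757, -3.53 for bll6061 and -4.15 for bll7696, while the other measured fixK gene (bll3466) stood at 0.50, fixC (blr1774) at 0.16 and fixR (blr2036) at 0.88. Low as well were nirK (blr7089) at -4.96, cycB (blr6128) at -4.99 and phbC (bll6073) at -4.65. A fault of a single array is argued against by the median on the replicate 2 array closer to 0, which was -4.35. The spread (MAD) over all genes was alike in replicates 1 and 2, at 0.450 and 0.473. This argues against a wider scale of most genes. The array SDs, which also reflect extreme values, were 0.97 and 0.92 in replicate 2 against 0.69 and 0.67 in replicate 1. The median of the 11 genes divided by the MAD differed between these replicates by -8.20. Those genes were chosen after their values were seen, so this difference decides nothing. A difference between the cultures of replicate 2, for example in oxygen, could be a cause and was not tested.

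Ribosomal protein and ATP synthase genes were higher with paraquat, and a bias shared by genes measured on all 6 arrays could raise both. Against this, the 30 ribosomal protein genes measured on all 6 arrays had a median above those of all 10000 random lists of such genes. The 5 ATP synthase genes lay at the percentile 99.99. The random lists hold unrelated genes, while the estimated correlation between genes was 0.82 in the ATP synthase list and 0.12 in the ribosomal protein list. Lists of correlated genes vary more than random ones, so these percentiles may be too extreme. A bias of bright spots stays open because intensities were not used here, and a difference in growth between treated and untreated cultures stays open as untested.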
